A study of Mus musculus with 23 samples.

How the data were processed

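Polyadenylated RNA was sequenced from flash-frozen livers of 23 C57Bl/6J mice, with 1 library per animal. Per the labels, RNA was isolated with a column kit that includes a DNase step, and libraries were made with a directional kit. The deposited table holds 49585 Ensembl mouse genes in 23 columns, each column named for 1 sample, and no column was left without a sample. Per the submitters' processing notes, FastQC, STAR, HTSeq and DESeq2 were used, without versions. Which tool did which step, the genome build and annotation, and whether counting used the strand or reads with several matches are not given in the sources used here.

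The deposited values are whole-number counts per gene, and they were read as raw counts although the table is named as normalised. Each library held every whole number from 1 to 100, genes with 1 count outnumbered genes with 2 by 1.80-fold to 2.25-fold, and the size factors that DESeq2's method gives on the values ranged from 0.623 to 1.43, whereas values already scaled that way would give factors near 1. The design had allowed for either unit, and the test written for counts was therefore used. No gene-free summary lines were present. Symbols were taken from a table of Ensembl identifiers, which matched 49326 genes. The 259 genes without a symbol held 0.0137% of the counts. Library totals ranged from 16876460 to 34527932 counts, and 26798 genes had a count in some library.

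Samples were grouped by the treatment named in their labels, and library names such as MetS-MetS_110 are those of the labels. Sex, litter and the dam's time on diet (7 or 17 weeks) could not be used as covariates, as they are not given per animal in the sources used here. A planned covariate for sex was not run, because all libraries fell in 1 class, female, by Xist and the Y-linked genes. Animal numbers are not shared between groups and pair no samples. Pairs of libraries within a group had Pearson correlations of 0.944 to 0.988 in log CPM and differed by more than sampling noise, with a chi-square of at least 17.8 per gene, and each was counted as 1 replicate.

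Genes with a mean of at least 10 counts over the 23 libraries were tested, 14466 in all. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with TMM factors, robust estimation and 1 mean per group over all 23 libraries, so that all comparisons share 1 estimate of the spread. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were derived from the fold change and the F statistic. The comparisons were MetS-Ct, Ct-MetS and MetS-MetS against Ct-Ct, MetS-Ct against Ct-MetS, prenatal exposure averaged over both postnatal states, postnatal exposure averaged over both prenatal states, and the interaction. CPM values use effective library sizes. The precision this depth and group size give was tested on simulated counts drawn independently for each library, with 200 of the genes changed. Changes of 1.5-fold, 2-fold and 4-fold were recovered at 46.3%, 74.6% and 93.9% in Ct-MetS (14394 genes, 8 false calls). In MetS-MetS recovery was 46.3%, 79.1% and 98.5% (14387 genes, 3 false calls). In MetS-Ct it was 35.8%, 71.6% and 98.5% (14386 genes, 6 false calls).

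Gene lists (38) cover imprinted genes, lipid and carbohydrate metabolism, fibrosis, cell types of the liver, stress and sex-biased expression. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 on log2(normalised count + 1), and 37 lists met that minimum. Camera with an estimated correlation and fry were alternatives. Adjusted p values beside list medians come from camera with an estimated correlation. Separation of the groups was measured as the share of squared distance between groups on the same log2 values, with 100000 permutations of the labels. Relations of Plagl1 were computed as Pearson and Spearman correlations with the mean z-score of 3 lists after group means were removed, with 100000 permutations within groups. Overlaps between comparisons with shared controls were set against 50 simulations of unchanged groups.

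Genes named in the text were chosen by a rule. In each comparison of groups it takes the 6 higher and 6 lower called genes with the largest log2 fold change among those with a mean count of at least 50, or the 6 with the smallest p where none passed. For prenatal and postnatal exposure and the interaction it takes the 5 genes with the smallest p. It adds up to 4 members of each described list by smallest p, and always Plagl1, Igf2, H19, Cdkn1c, Dlk1, Tgfb1, Col1a1, Col3a1, Srebf1, Fasn and Cyp7a1. Predicted genes, bare identifiers, pseudogenes and genes of the sex chromosomes used for typing were left out, and some genes that the rule takes are not reported here. Other genes named in passing, among them Klf1, Alas2, Sptb and Dbp, were chosen after their values were seen. The rule was applied again without MetS-MetS_110.

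The groups, the tests, the 38 lists, the naming rule and most alternatives were fixed before the data were examined. These alternatives were no filter, a mean count of at least 50, DESeq2 1.42.0 Wald tests, limma-voom with sample weights, limma-trend with pseudocounts of 0.5 and 5, edgeR without robust estimation, fits to the groups compared alone, and leaving out each library in turn. Added after seeing the data were DESeq2 size factors in edgeR, counts thinned to the smallest library, 2 principal components of the clock list as covariates, both MetS-MetS_110 and Ct-MetS_169 left out, and MetS-MetS_110 left out with each other library in turn for the genes named without it. Labels were also reassigned at random, giving 100 splits with the real one included. No library was left out of the main test.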

Results

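Liver messenger RNA was measured in 23 C57Bl/6J mice at weaning, grouped by the time at which they had been exposed to maternal metabolic syndrome (MetS). Per the labels, the dams ate a diet with 10% or 45% fat from 3 weeks of age, and litters of 5 pups were moved to foster dams at birth. Pups with neither exposure form Ct-Ct (n = 6), pups exposed before birth form MetS-Ct (n = 6), pups exposed while nursed by the foster dam form Ct-MetS (n = 6), and pups exposed at both times form MetS-MetS (n = 5). MetS-Ct_97 is labelled postnatal day 22 and every other animal day 21. Library totals ranged from 16876460 to 34527932 counts, with means of 27005778 ± 1222640 (SD) in Ct-Ct, 27651612 ± 2961414 in MetS-Ct, 28312879 ± 4284623 in Ct-MetS and 22298680 ± 4696465 in MetS-MetS. Libraries carry animal numbers, whereas sex, litter and the length of the dam's diet are not given per animal in the sources used here. Siblings among the pups would make p-values too small. In every library Xist, the transcript of the inactive X chromosome, was at 907 CPM (counts-per-million) or more and the Y-linked Ddx3y had at most 1 count. By these transcripts all 23 animals were female.

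The 4 groups accounted for 22.5% of the variance between libraries in log expression (permutation p = 7e-04, one-sided for a share as large, 100000 permutations). Random labels also give some share, which the permutation p takes into account. Of 14466 genes tested, 611 differed with postnatal exposure averaged over both prenatal states (329 higher, 282 lower) and 1 with prenatal exposure averaged over both postnatal states. For prenatal exposure, mean over both postnatal states, DESeq2 called 140 and limma-voom 218, and for postnatal exposure, mean over both prenatal states, 1038 and 1465. Against Ct-Ct, 0 genes passed in MetS-Ct, 138 in Ct-MetS and 836 in MetS-MetS. Of 37 gene lists, camera with a preset correlation passed 16 in MetS-Ct, 16 in Ct-MetS, 15 in MetS-MetS, 18 in MetS-Ct against Ct-MetS, 13 with prenatal exposure, 16 with postnatal exposure and 19 for the interaction. With an estimated correlation the erythroid list alone passed, with postnatal exposure and in MetS-Ct against Ct-MetS.

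Postnatal exposure was addressed first by comparing the 11 pups nursed by MetS dams with the 12 nursed by control dams. Ucp2, a carrier of the inner mitochondrial membrane, rose 1.61-fold (log2 fold change 0.69 ± 0.073 SE, adjusted p = 2.97e-05), from 31.2 ± 4.16 (SD) CPM in Ct-Ct and 36.8 ± 3.19 in MetS-Ct to 52.0 ± 8.38 in Ct-MetS and 57.6 ± 4.44 in MetS-MetS. Il1rn, which encodes the antagonist of the interleukin 1 receptor, rose 3.60-fold (log2 fold change 1.85 ± 0.29 SE, adjusted p = 0.00147), from 2.34 ± 1.28 CPM in Ct-Ct to 9.39 ± 5.74 in Ct-MetS and 9.47 ± 2.20 in MetS-MetS. Slc4a1, the anion exchanger of the red cell membrane, rose 3.16-fold (1.66 ± 0.21, adjusted p = 0.000308). The protease inhibitor gene Serpina3g rose by 0.70 ± 0.097 on the log2 scale (adjusted p = 0.000462). Smoc2, which encodes a secreted calcium-binding matrix protein, fell 2.15-fold (−1.10 ± 0.15, adjusted p = 0.000459), from 57.5 ± 12 CPM in Ct-Ct to 27.6 ± 5.11 in Ct-MetS and 20.7 ± 6.97 in MetS-MetS. The mitochondrial carrier gene Sfxn5 fell by 0.53 ± 0.076 (adjusted p = 0.000566). Each of these genes lay on the side of its change in 11 of 11 exposed libraries, relative to the mean of the unexposed ones. Each kept its call when any 1 of the 23 libraries was left out.

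Of 42 measured genes of fatty acid oxidation and ketogenesis 19 rose with postnatal exposure and 0 fell over all genes. When adjusted over the list alone 35 rose, and the list had a median log2 fold change of 0.51. The list passed camera with a preset correlation between genes, but did not pass with an estimated correlation (adjusted p = 0.198). Decr1, an enzyme of polyunsaturated fatty acid oxidation, rose 1.49-fold (log2 fold change 0.57 ± 0.098 SE, adjusted p = 0.00269). Aldh3a2, the fatty aldehyde dehydrogenase, rose 1.71-fold (0.77 ± 0.14, adjusted p = 0.0032). Vnn1, a pantetheinase induced by PPAR-alpha, rose 3.68-fold (1.88 ± 0.34, adjusted p = 0.00596). Hadha, a subunit of the mitochondrial trifunctional protein, rose 1.26-fold. These calls were kept without any 1 library, and each gene was higher in 10 of 11 exposed libraries.

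Part of the genes of fatty acid and triglyceride synthesis moved the other way. Of 27 measured members 8 fell and 1 rose over all genes, and 14 fell and 2 rose when adjusted over the list alone (median log2 fold change −0.88, adjusted p = 0.476 with an estimated correlation). Scd1, the stearoyl-CoA desaturase, fell by 2.15 ± 0.49 on the log2 scale (adjusted p = 0.017), from 13330 ± 8961 CPM in Ct-Ct and 7627 ± 5947 in MetS-Ct to 2674 ± 966 in Ct-MetS and 1938 ± 650 in MetS-MetS. Acaca, which encodes acetyl-CoA carboxylase, fell by 1.30 ± 0.31 (adjusted p = 0.0207). Pnpla3, a lipid droplet acylhydrolase, fell by 2.45 ± 0.53 (adjusted p = 0.0133), and Mlxipl, which encodes the carbohydrate response factor ChREBP, fell by 0.46 ± 0.10 (adjusted p = 0.0134). All 4 were lower in 11 of 11 exposed libraries, relative to the mean of the unexposed ones. The ranges overlapped, as the unexposed MetS-Ct_70 and MetS-Ct_97 had Scd1 at 318 and 940 CPM, below the lowest exposed library (1266 in MetS-MetS_109). Their Acaca (81.9 and 81.7 CPM) and Pnpla3 (3.59 and 3.35 CPM) lay within the range of the exposed libraries. The member that rose was Fads2, a desaturase of polyunsaturated fatty acids (0.80 ± 0.22, adjusted p = 0.0449), whose call was lost without most single libraries and reached an adjusted p of 0.0851 without MetS-MetS_157. Fasn, the fatty acid synthase, lay at −1.60 ± 0.46 with an adjusted p of 0.0532, and Srebf1, a transcription factor for these enzymes, at −0.082 ± 0.22 (adjusted p = 0.87). Among 29 genes of gluconeogenesis, glycogen and the insulin response, 4 fell, and 5 when adjusted over the list alone (adjusted p = 0.476 with an estimated correlation). They included Gckr, which encodes the glucokinase regulatory protein (−0.53 ± 0.077, adjusted p = 0.000613), the fructose enzyme Khk (−0.94 ± 0.16, adjusted p = 0.0032) and the liver glycogen phosphorylase Pygl (−0.56 ± 0.12).

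Erythroid genes rose with postnatal exposure in 10 of 22 measured members, and in 13 (1 lower) when adjusted over the list alone, with a median log2 fold change of 0.47 and adjusted p = 0.0149 with an estimated correlation. Besides Slc4a1 these included genes for other proteins of the red cell membrane, namely Rhag (log2 fold change 2.50 ± 0.36 SE, adjusted p = 0.000566), Kel (2.23 ± 0.32, adjusted p = 0.000566) and Ermap (1.87 ± 0.25, adjusted p = 0.000317), all higher in 11 of 11 exposed libraries. Their levels were low: Rhag was at 0.168 ± 0.12 CPM in Ct-Ct and 0.838 ± 0.49 in MetS-MetS. After thinning every library to the smallest total 5 of the 10 were still called, and the median log2 fold change of the 10 was 1.70 against 1.79 before. Rhag and Rhd fell under the count minimum without Ct-MetS_50. Rhag lost its call without MetS-MetS_39 or MetS-MetS_157, Rhd without Ct-MetS_145 or MetS-MetS_39, and the spectrin gene Sptb without 17 of the 23 libraries (adjusted p up to 0.0899, without MetS-MetS_110). The globin genes Hba-a1 (0.37 ± 0.19, adjusted p = 0.266) and Hbb-bs (0.38 ± 0.18, adjusted p = 0.232), the haem synthesis gene Alas2 (0.27 ± 0.14, adjusted p = 0.272) and the erythroid factor Klf1 (−0.39 ± 0.17, adjusted p = 0.179) did not pass. The mean log2 fold change of 4 globin genes was −0.46 (mean SE 0.257) in pups not exposed before birth and 1.31 (mean SE 0.271) in pups exposed before birth.

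Of 25 Kupffer cell and macrophage markers, 9 rose with postnatal exposure and 17 when adjusted over the list alone (median log2 fold change 0.31, adjusted p = 0.198 with an estimated correlation). Cd68, a lysosomal glycoprotein of macrophages, rose 1.48-fold (0.57 ± 0.090, adjusted p = 0.00147). The macrophage surface gene Adgre1 rose 1.42-fold (0.51 ± 0.092, adjusted p = 0.00468). In the same comparison 0 of 17 neutrophil and monocyte markers and 0 of 24 lymphocyte markers passed by edgeR or DESeq2, with 2 and 5 at an unadjusted p under 0.05 and medians of 0.043 and 0.15. Emcn, 1 of 25 endothelial markers, passed (adjusted p = 0.0469, kept without 5 of the 23 libraries). Among 32 cell cycle genes Ccnb2, a mitotic cyclin, passed (1.02 ± 0.26, adjusted p = 0.0304, lost without Ct-Ct_4 or Ct-Ct_129, Ct-MetS_24 or MetS-MetS_110 or MetS-MetS_154), and 16 rose when adjusted over the list alone (median 0.58, adjusted p = 0.465 with an estimated correlation). For postnatal exposure, mean over both prenatal states, leaving out 1 library gave between 349 calls, without MetS-MetS_154, and 923, without Ct-MetS_50. The count fell more than 1.5-fold also without Ct-Ct_4 (394) or Ct-Ct_129 (359) and Ct-MetS_24 (407), Ct-MetS_145 (391) or Ct-MetS_169 (402).

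**Figure D1:**
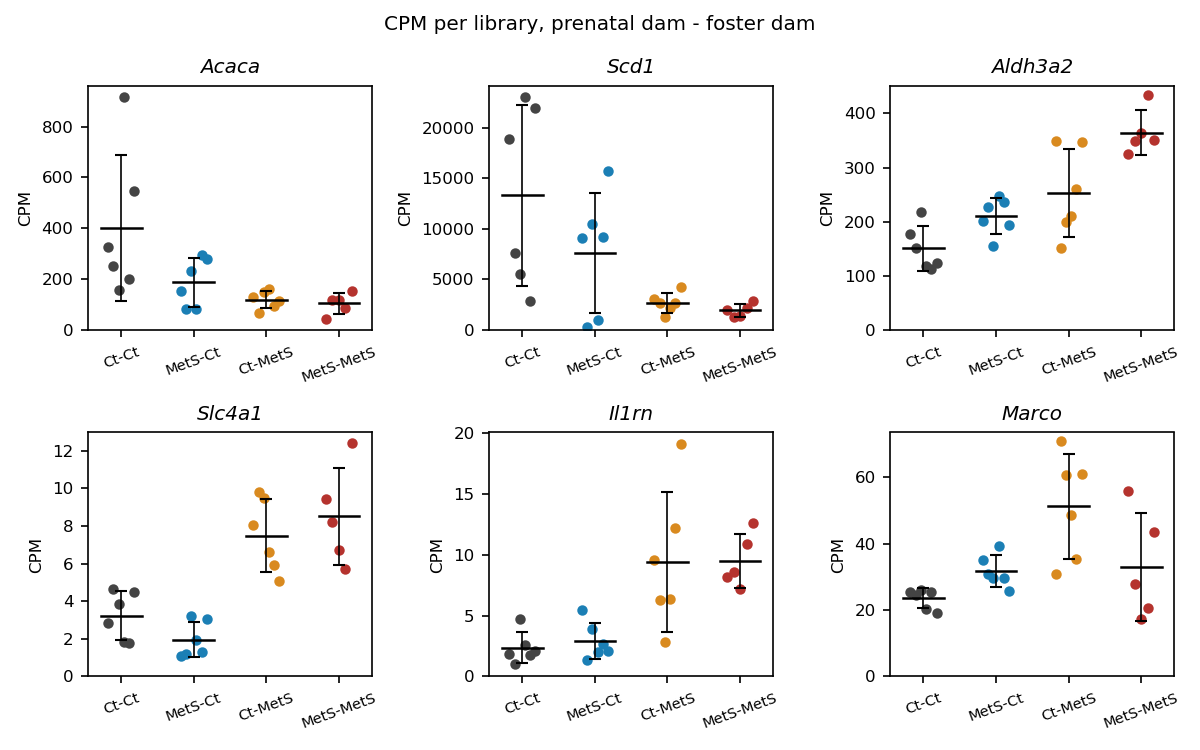
CPM in each library for Acaca, Scd1, Aldh3a2, Slc4a1, Il1rn and Marco, with 1 point per animal in the 4 groups, a line at the group mean and bars of ± 1 SD. Scd1 lay at 1938 ± 650 CPM in MetS-MetS and 13330 ± 8961 in Ct-Ct.

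Postnatal exposure alone, in Ct-MetS against Ct-Ct, gave 85 genes higher and 53 lower. Il1rn was 4.01-fold higher (log2 fold change 2.0 ± 0.40 SE, adjusted p = 0.0224). Marco, a scavenger receptor of macrophages, was 2.18-fold higher (1.12 ± 0.24, adjusted p = 0.0267), at 51.2 ± 15.8 CPM against 23.5 ± 3.03. Fabp7 (1.22 ± 0.25, adjusted p = 0.023) and Fabp2 (1.11 ± 0.23, adjusted p = 0.0231), which encode the brain and intestinal forms of fatty acid binding protein, were higher. The family as a whole was not tested. Slc4a1 was 2.32-fold higher (1.22 ± 0.29, adjusted p = 0.0427). Gpc1, a cell surface heparan sulphate proteoglycan, rose by 1.10 ± 0.23 (adjusted p = 0.0242). Acaca was 3.38-fold lower (−1.76 ± 0.43, adjusted p = 0.0494). Of the genes for fructose use Khk was 2.43-fold lower (−1.28 ± 0.23, adjusted p = 0.0187), at 315 ± 124 CPM against 764 ± 151, and Tkfc was 2.47-fold lower (−1.30 ± 0.25, adjusted p = 0.0187). Prodh, the proline dehydrogenase, was 2.13-fold lower (−1.09 ± 0.21, adjusted p = 0.0187). Rnd2 (−1.12 ± 0.25, adjusted p = 0.031) and Zc3h6 (−1.07 ± 0.26, adjusted p = 0.0419) were lower too. All 12 genes moved in the same direction in 6 of 6 Ct-MetS libraries, relative to the Ct-Ct mean.

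Kupffer cell and macrophage markers rose in 8 of 25 members in Ct-MetS, and in 17 when adjusted over the list alone (median 0.41, adjusted p = 0.112 with an estimated correlation). Cd68 lay at 0.70 ± 0.13 (adjusted p = 0.0187) and Adgre1 at 0.63 ± 0.13 (adjusted p = 0.0224). In the list of gluconeogenesis, glycogen and insulin response genes 4 of 29 fell, both over all genes and adjusted over the list alone (median −0.18, adjusted p = 0.238 with an estimated correlation), among them Khk, Gckr and Pygl. Of 22 erythroid genes 5 rose, and 8 when adjusted over the list alone (median 0.30, adjusted p = 0.265 with an estimated correlation). After thinning to the smallest library 1 of these 5 was still called, with a median log2 fold change of 1.87 against 1.93 over the 5. Of the 27 members of the synthesis list 2 passed, Acaca and Tkfc, of which Tkfc encodes an enzyme of fructose use. When adjusted over the list alone 12 were lower and 2 higher (median −1.16, adjusted p = 0.331 with an estimated correlation). For fatty acid oxidation 0 of 42 passed by edgeR over all genes, with 24 at an unadjusted p under 0.05 and 7 called by DESeq2, and 19 rose when adjusted over the list alone (median 0.45, adjusted p = 0.238 with an estimated correlation). Pcolce, an enhancer of procollagen processing (0.62 ± 0.13, adjusted p = 0.0224), and Sparc, a collagen-binding protein (0.35 ± 0.078, adjusted p = 0.0273), rose among 38 extracellular matrix genes, of which 8 rose when adjusted over the list alone (median 0.30, adjusted p = 0.331 with an estimated correlation). Of 32 cell cycle genes 0 passed over all genes by edgeR, with 17 at an unadjusted p under 0.05 and 6 called by DESeq2, and 10 did when adjusted over the list alone (median 0.69, adjusted p = 0.385 with an estimated correlation).

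The number of calls in Ct-MetS varied with single libraries. Of 138 calls 12 were left without Ct-MetS_169, a library with H19 at 4551 CPM, 26 without Ct-Ct_10, 43 without Ct-Ct_4, 46 without Ct-Ct_139, 56 without Ct-Ct_129 and 80 without Ct-MetS_63, against 246 without Ct-Ct_33. Ucp2, Cd68 and Khk kept their calls without any 1 library, whereas Acaca kept its call without 6 of the 23 libraries, Slc4a1 and Zc3h6 without 10 and Rnd2 without 15. Il1rn was lost without Ct-Ct_4, Ct-Ct_10 or Ct-Ct_139 or Ct-MetS_169, Marco without these or Ct-Ct_129 or Ct-MetS_63, and Prodh without Ct-Ct_10. Gckr kept its call without 22 of the 23 libraries, Tkfc without 21, Fabp7, Pcolce and Adgre1 without 20, Gpc1 without 19, Fabp2 without 18 and Sparc without 16. Pygl was lost without Ct-Ct_4, Ct-Ct_10, Ct-Ct_129 or Ct-Ct_139 or Ct-MetS_145 or Ct-MetS_169. Without Ct-MetS_169 called members numbered 0 of the erythroid list, 1 of the Kupffer list, 1 of the gluconeogenesis list and 0 of the synthesis list. The genes called with all libraries then had median log2 fold changes of 2.01 against 1.93 (erythroid), 0.56 against 0.59 (Kupffer) and −1.48 against −1.53 (synthesis). Erythroid calls were 0 without Ct-Ct_10 or Ct-Ct_139, 1 without Ct-Ct_4 or Ct-Ct_129 or Ct-MetS_50, 2 without Ct-MetS_145 and 3 without Ct-Ct_130, MetS-Ct_97, Ct-MetS_24, Ct-MetS_63 or Ct-MetS_65 or MetS-MetS_39 or MetS-MetS_109. Kupffer calls were 1 without Ct-Ct_10 or Ct-Ct_139, 3 without Ct-Ct_129, 4 without Ct-Ct_4 and 5 without Ct-MetS_63 or Ct-MetS_145. Gluconeogenesis calls were 2 without Ct-Ct_10, and for fatty acid oxidation 5 genes were called without Ct-Ct_33 and 8 without Ct-MetS_50. The synthesis count was 5 without Ct-Ct_33, 4 without Ct-Ct_130 or MetS-Ct_70, 3 without MetS-Ct_97, 2 without MetS-Ct_120 or MetS-Ct_149 or MetS-MetS_39, 0 without Ct-MetS_169 and 1 without any other library.

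Exposure at both times, in MetS-MetS against Ct-Ct, gave 443 genes higher and 393 lower. The lowest relative to Ct-Ct included Pnpla3, 13.1-fold lower (log2 fold change −3.71 ± 0.82 SE, adjusted p = 0.0168), at 2.62 ± 1.18 CPM against 34.1 ± 30.5, and Elovl6, a fatty acid elongase, by 12.9-fold (−3.68 ± 0.94, adjusted p = 0.0278). Scd1 was 6.88-fold lower (−2.78 ± 0.73, adjusted p = 0.0307) and Fasn was 6.04-fold lower (−2.59 ± 0.70, adjusted p = 0.0352). Hamp2, a gene of the hepcidin family with a close paralog, was 11.9-fold lower (−3.57 ± 1.02, adjusted p = 0.0439). Chrna4, a nicotinic receptor subunit, was 16.0-fold lower (−4.0 ± 1.15, adjusted p = 0.0456). Acss2os, transcribed opposite to the acetyl-CoA synthetase gene, lay at −3.79 ± 1.07 (adjusted p = 0.0419), though whether the counting used the strand is not given in the sources used here. Each was lower than the Ct-Ct mean in 5 of 5 MetS-MetS libraries, though single libraries overlapped for some genes. Fasn was at 298 CPM in Ct-Ct_33 and 383 in MetS-MetS_157, and Chrna4 at 6.17 in Ct-Ct_130 and 9.75 in MetS-MetS_154. Hamp2 was at 1.88 CPM in Ct-Ct_139 and 3.94 in MetS-MetS_157. Pnpla3, Elovl6 and Scd1 lay below every Ct-Ct library in all MetS-MetS libraries. Elovl6 lay at −2.96 (adjusted p = 0.0772) without Ct-Ct_129 and Hamp2 at −4.62 without MetS-MetS_157. The largest increases, in Krt13 (log2 fold change 12.61 ± 2.50 SE), Krt4, Acta1, Ckm, Myh1 and Tnnt3, which encode keratins of squamous epithelium and proteins of skeletal muscle, came from the library of MetS-MetS_110 alone (Krt13 at 13.81 without Ct-Ct_139). It held 339 CPM of Krt13 and 358 CPM of Acta1, against at most 0.055 CPM in the other 4 libraries of the group.

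Without MetS-MetS_110, 326 genes passed (211 higher, 115 lower), 313 of them among the 836, and none of these 6 genes did. The largest increases, named after the data were seen, were then in Acot1, an acyl-CoA thioesterase of the cytosol (12.1-fold, log2 fold change 3.60 ± 0.64 SE, adjusted p = 0.0114), Cyp4a10, a fatty acid omega-hydroxylase (8.92-fold, 3.16 ± 0.80, adjusted p = 0.0447), Acot3 (5.87-fold, 2.55 ± 0.66, adjusted p = 0.0469), Vnn1 (4.87-fold, 2.28 ± 0.53, adjusted p = 0.0303), Chrna2 (2.11 ± 0.48, adjusted p = 0.0266) and Il1rn (2.10 ± 0.44, adjusted p = 0.0195). The largest decreases were in Pnpla3 (−3.76), Acaca (−1.99), Smoc2 (−1.60 ± 0.23, adjusted p = 0.00265), Zc3h6 (−1.33), Tkfc (−1.25) and Slc51b (−1.20), a basolateral bile acid transporter subunit. Cyp4a10 stood at 889 ± 1182 CPM in these 4 libraries, with 2640 in MetS-MetS_39, against 99.6 ± 61.7 in Ct-Ct, and Acot1 at 31.9 ± 38.7 against 2.64 ± 0.91. Without MetS-MetS_39 as well, Cyp4a10 lay at 1.61 (3.06-fold, adjusted p = 0.231) and Acot1 at 2.27 (4.83-fold, adjusted p = 0.0494), and without Ct-Ct_4 as well Acot3 lay at 3.21 (9.28-fold). Of the 22 remaining libraries, leaving out 1 more kept the call of Acot1 and Smoc2 each time, of Chrna2, Il1rn and Tkfc in 18 cases, Zc3h6 in 17, Vnn1 in 16, Pnpla3 in 15, Acaca and Slc51b in 11, Cyp4a10 in 10 and Acot3 in 6. Acot and Cyp4a genes have close paralogs, and how reads shared between them were counted is not given in the sources used here.

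Fatty acid oxidation and ketogenesis genes rose in 29 of 42 members in MetS-MetS, and in 37 when adjusted over the list alone (median log2 fold change 0.82, adjusted p = 0.199 with an estimated correlation). Aldh3a2 rose 2.42-fold (1.28 ± 0.20, adjusted p = 0.00257), from 150 ± 41.4 to 365 ± 41.6 CPM. Decr1 rose 1.84-fold (0.88 ± 0.14, adjusted p = 0.0036). Cpt2 (0.91 ± 0.17, adjusted p = 0.00724) and Cpt1a (0.90 ± 0.19, adjusted p = 0.012), the carnitine acyltransferases that bring fatty acids into mitochondria, rose too. In the synthesis list 10 of 27 fell, and 13 fell with 1 higher when adjusted over the list alone (median −0.75, adjusted p = 0.56 with an estimated correlation). Mlxipl lay at −0.75 ± 0.15 (adjusted p = 0.0105) and Acaca fell too (adjusted p = 0.0202). Of 25 cholesterol synthesis genes 0 passed by edgeR over all genes, adjusted over the list alone or by DESeq2, with 5 at an unadjusted p under 0.05 (median −0.66, adjusted p = 0.798 with an estimated correlation). Lipid droplet and lipid uptake genes rose in 5 of 22 members and in 7 when adjusted over the list alone (median 0.62, adjusted p = 0.252 with an estimated correlation), among them the monoacylglycerol lipase Mgll (0.88 ± 0.20, adjusted p = 0.0179) and Fitm2, needed for droplet budding (0.94 ± 0.22, adjusted p = 0.02). In the same libraries the clock gene Dbp, whose liver transcript cycles over the day, stood at 267 CPM in MetS-MetS_109, 198 in MetS-MetS_110, 169.3 in MetS-MetS_157, 71.8 in MetS-MetS_154 and 2.78 in MetS-MetS_39, against 9.66 to 40.3 in Ct-Ct. With the 2 main components of the clock list as covariates, added after the data were seen, 8 of the 29 oxidation genes and 1 of the 10 synthesis genes were still called. The median log2 fold change of the 29 was then 0.91 (median SE 0.232) against 0.90 (0.197) without covariates, and that of the 10 was −1.50 (0.770) against −2.53 (0.668).

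Of the other groups, 10 of 25 Kupffer cell and macrophage markers rose in MetS-MetS, and 15 when adjusted over the list alone (median 0.38, adjusted p = 0.252 with an estimated correlation), among them Folr2 (0.64 ± 0.13, adjusted p = 0.0105) and Cd68 (0.65 ± 0.13, adjusted p = 0.0107). Erythroid genes rose in 8 of 22 members and in 11 when adjusted over the list alone (median 0.36, adjusted p = 0.199 with an estimated correlation), with Kel at 2.40 ± 0.46 (adjusted p = 0.00841) and Ermap at 1.79 ± 0.35 (adjusted p = 0.0105). With the clock components as covariates 2 of the 10 Kupffer markers and 2 of the 8 erythroid genes were called. Their median log2 fold changes were 0.50 (median SE 0.154) against 0.56 (0.129) without covariates for the Kupffer markers, and 2.01 (0.528) against 1.89 (0.411) for the erythroid genes. After thinning 5 of the 8 erythroid genes were still called (median 1.72). Gckr (−0.74 ± 0.11, adjusted p = 0.00257), Khk (−1.01 ± 0.24, adjusted p = 0.0198) and Pygl (−0.66 ± 0.18, adjusted p = 0.0334) fell among 29 gluconeogenesis genes, and 4 fell with 1 higher when adjusted over the list alone (median 0.005, adjusted p = 0.848 with an estimated correlation). The skeletal muscle list had 12 of 14 members higher with all libraries, 13 when adjusted over the list alone (median 6.53, adjusted p = 0.798 with an estimated correlation), and 0 without MetS-MetS_110 by edgeR, where 3 members were still above the count minimum and 0 had an unadjusted p under 0.05. DESeq2 called 0 of the 14 with all libraries. In groups of this size it can leave a gene with a count far from the rest without a p value. Its 0 calls are therefore not a test without MetS-MetS_110.

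The 836 calls of MetS-MetS against Ct-Ct fell to 219 without Ct-Ct_129, 323 without Ct-Ct_139, 326 without MetS-MetS_110, 382 without MetS-MetS_157, 417 without Ct-Ct_4 and 537 without MetS-MetS_154, and rose to 1354 without Ct-Ct_33. Called oxidation genes numbered 17 without Ct-Ct_129 and 19 without Ct-Ct_139, and synthesis genes 3 without Ct-Ct_129, 4 without Ct-Ct_139 or MetS-MetS_110, MetS-MetS_154 or MetS-MetS_157 and 6 without MetS-MetS_109. Kupffer markers numbered 3 without Ct-Ct_129, 4 without MetS-MetS_157, 5 without Ct-Ct_139 and 6 without MetS-MetS_39, erythroid genes 5 without MetS-MetS_157, and gluconeogenesis genes 1 without Ct-Ct_129. Lipid droplet genes numbered 0 without Ct-Ct_129, 2 without Ct-Ct_139 and 3 without Ct-Ct_4 or MetS-MetS_110. Aldh3a2, Decr1, Cpt1a, Cpt2, Vnn1, Acot1, Mlxipl, Pnpla3, Gckr, Cd68, Folr2, Kel, Ermap, Ucp2 and Il1rn kept their calls without any 1 library. Acaca, Khk, Mgll and Fitm2 were lost without Ct-Ct_129, Elovl6 without that library, Ct-Ct_139 or MetS-MetS_109, MetS-MetS_110, MetS-MetS_154 or MetS-MetS_157, and Pygl without Ct-Ct_4, Ct-Ct_129 or Ct-Ct_139 or MetS-MetS_39, MetS-MetS_110, MetS-MetS_154 or MetS-MetS_157. Scd1, Fasn and Acss2os kept their calls without 15 of the 23 libraries, Hamp2 without 14 and Chrna4 without 9.

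**Figure D2:**
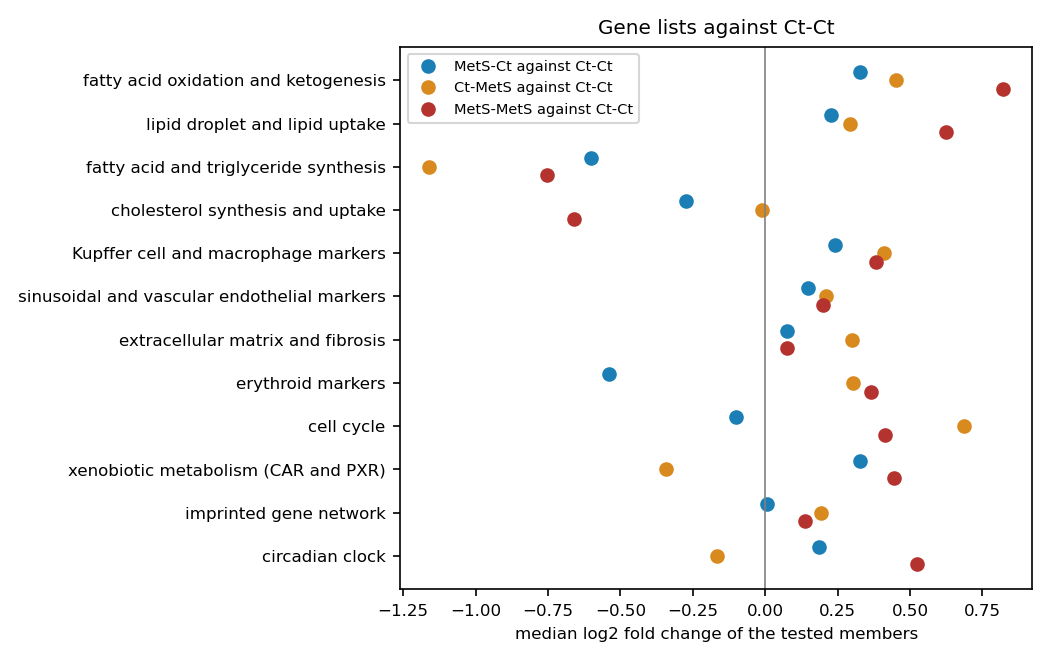
Median log2 fold change of the members of 12 gene lists in MetS-Ct, Ct-MetS and MetS-MetS, each against Ct-Ct (n = 6, 6, 6 and 5 libraries). Oxidation genes lay at 0.33, 0.45 and 0.82, and synthesis genes at −0.60, −1.16 and −0.75.

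Exposure before birth alone, in MetS-Ct against Ct-Ct, gave 0 calls by edgeR, with 854 genes at an unadjusted p under 0.05 where 723 would be expected by chance, and 12 calls by DESeq2 (1 higher, 11 lower). The smallest adjusted p was 0.318, shared by Rhbdd1, a rhomboid protease (log2 fold change −0.34 ± 0.069 SE, 19.8 ± 1.55 CPM against 25.0 ± 1.73), Gtf2b, a general transcription factor (−0.53 ± 0.11), the globin gene Hbb-bt (−1.27 ± 0.26, 21.4 ± 5.06 CPM against 51.6 ± 24.7), the phosphoinositide-binding Plekha1 (−0.46 ± 0.10) and the tRNA synthetase genes Gars (−0.34 ± 0.073) and Lars (−0.29 ± 0.065). Erythroid genes were the list with most members past the threshold when adjusted over the list alone, 7 lower of 22, with 0 over all genes by edgeR, 8 at an unadjusted p under 0.05 and 4 by DESeq2 (median −0.54, adjusted p = 0.215 with an estimated correlation), and these included Hbb-bt, Hba-a2 (−1.16 ± 0.26), Hba-a1 (−1.09 ± 0.27) and Hbb-bs (−1.02 ± 0.25). Cyp2b10, a target of the xenobiotic receptor CAR, lay at 3.25 ± 0.77 (adjusted p = 0.404, and 0.0109 adjusted over the list alone). Oxidation genes had a median of 0.33 (adjusted p = 0.376 with an estimated correlation) and synthesis genes of −0.60 (adjusted p = 0.45 with an estimated correlation), with 0 members of either past the threshold by edgeR or DESeq2, and 13 and 7 at an unadjusted p under 0.05. Simulated genes changed 1.5-fold, 2-fold and 4-fold in this comparison were recovered at 35.8%, 71.6% and 98.5%. The simulation changed 200 genes and drew each library independently. Where fewer genes change the adjusted threshold is stricter, so these shares do not exclude changes of such size here.

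Averaged over both postnatal states, prenatal exposure lowered Plekha1 1.4-fold (log2 fold change −0.48 ± 0.075 SE, adjusted p = 0.0217, lower in 11 of 11 exposed libraries), from 28 ± 3.50 CPM in Ct-Ct and 24.1 ± 3.82 in Ct-MetS to 20.3 ± 1.74 in MetS-Ct and 17.1 ± 1.99 in MetS-MetS. The next genes, at an adjusted p of 0.126, were Asns, the asparagine synthetase (−0.67 ± 0.13), the chromatin factor Arid5b (0.51 ± 0.10), the pore-forming Gsdme (−0.73 ± 0.15) and Lars (−0.24 ± 0.048). Oxidation genes had 0 calls over all genes by edgeR, 31 at an unadjusted p under 0.05 and 2 by DESeq2, and 26 higher and 1 lower when adjusted over the list alone (median 0.33, adjusted p = 0.403 with an estimated correlation). Xenobiotic genes had 0 calls by edgeR, 16 at an unadjusted p under 0.05 and 5 by DESeq2, and 12 higher when adjusted over the list alone (median 0.44, adjusted p = 0.0889 with an estimated correlation). Of 19 circadian clock genes 0 passed by edgeR, 9 had an unadjusted p under 0.05, DESeq2 called 3, and 5 were higher when adjusted over the list alone (median 0.32, adjusted p = 0.403 with an estimated correlation). In all, 2356 genes lay at an unadjusted p under 0.05, where 723 would be expected by chance. Plekha1 kept its call without 15 of the 23 libraries and reached an adjusted p of 0.0872 without MetS-MetS_109. It also lost its call with clock covariates (−0.49, adjusted p = 0.604) and after thinning (−0.46, adjusted p = 0.133). The count was 0 without Ct-Ct_129 or Ct-Ct_139, MetS-Ct_70, MetS-Ct_97 or MetS-Ct_149 or MetS-MetS_109, MetS-MetS_154 or MetS-MetS_157, 2 without Ct-MetS_24 or Ct-MetS_65 or MetS-MetS_110, and 22 without Ct-Ct_33.

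Exposure before birth was then set directly against exposure after birth. In MetS-Ct relative to Ct-MetS 11 genes passed, 6 higher and 5 lower. Slc4a1 was 3.80-fold lower (log2 fold change −1.93 ± 0.30 SE, adjusted p = 0.0236), at 1.96 ± 0.95 CPM against 7.49 ± 1.95. The erythroid genes Rhag (−2.70) and Ermap (−1.95) were lower too, as were Trim10 (−1.81) and Stom, a protein of the red cell membrane and other cells (−0.49 ± 0.090, adjusted p = 0.0343), which both lie outside the erythroid list. Ildr2, linked to lipid handling in the liver, was 2.50-fold higher (1.32 ± 0.22, adjusted p = 0.0285). Prodh (1.10 ± 0.21, adjusted p = 0.0348), Ggt6 (1.09 ± 0.19, adjusted p = 0.0285), Pgpep1l (1.44 ± 0.27, adjusted p = 0.0346) and Sfxn5 (0.58 ± 0.11, adjusted p = 0.0335) were higher. Of 22 erythroid genes 3 passed over all genes and 13 were lower with 1 higher when adjusted over the list alone (median −0.77, adjusted p = 0.014 with an estimated correlation). Cell cycle genes had 15 lower of 32 when adjusted over the list alone (median −0.80, adjusted p = 0.246 with an estimated correlation), and xenobiotic genes 13 higher and 1 lower of 30 (median 0.57, adjusted p = 0.199 with an estimated correlation), with 0 of either over all genes by edgeR, 21 and 15 at an unadjusted p under 0.05, and 1 each by DESeq2. By edgeR 0 genes were called with clock covariates (Slc4a1, MetS-Ct against Ct-MetS, at −1.82, adjusted p = 0.0856) and 0 in a fit of these groups alone, against 97 by DESeq2, with 1824 at an unadjusted p under 0.05 with all groups. Called genes numbered 0 without MetS-Ct_70, MetS-Ct_97 or MetS-Ct_120 or Ct-MetS_63, 1 without MetS-Ct_53 or Ct-MetS_145, 2 without Ct-MetS_24, 7 without MetS-MetS_39 or MetS-MetS_157, 17 without Ct-Ct_33, 23 without Ct-MetS_65, 28 without MetS-Ct_149 and 64 without Ct-MetS_50. Erythroid calls were 0 without MetS-Ct_53, MetS-Ct_70, MetS-Ct_97 or MetS-Ct_120 or Ct-MetS_63, 1 without Ct-MetS_24 or Ct-MetS_145, and 5 without MetS-Ct_85.

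The interaction, which tests whether postnatal exposure acts differently after prenatal exposure, gave 0 calls by edgeR, with 787 genes at an unadjusted p under 0.05, and 4 by DESeq2. The smallest adjusted p of 0.424 was shared by the globin genes Hba-a2 (log2 difference 1.91 ± 0.37 SE), Hbb-bt (1.78 ± 0.37) and Hba-a1 (1.78 ± 0.38), and by Adgrl3 (−1.0 ± 0.22) and Ntng2 (0.86 ± 0.19), which encode a latrophilin receptor and a netrin. Among erythroid genes 0 passed over all genes by edgeR, 8 had an unadjusted p under 0.05, 4 were called by DESeq2, and 5 were higher when adjusted over the list alone (adjusted p = 0.184 with an estimated correlation).

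Plagl1 (ENSMUSG00000019817), the imprinted zinc finger gene also called Zac1 that the series title names, stood at 7.43 ± 2.57 CPM in Ct-Ct, 7.74 ± 1.78 in MetS-Ct, 9.70 ± 2.25 in Ct-MetS and 8.30 ± 2.07 in MetS-MetS. Its log2 fold change was 0.38 ± 0.21 SE in Ct-MetS (adjusted p = 0.421), 0.16 ± 0.22 in MetS-MetS (adjusted p = 0.713), 0.060 ± 0.21 in MetS-Ct (adjusted p = 0.976) and 0.24 ± 0.15 with postnatal exposure (adjusted p = 0.381). Of 16 measured genes of the imprinted gene network, the set of imprinted genes expressed together around Plagl1, 0 passed in any comparison by edgeR over all genes. In Ct-MetS 4 had an unadjusted p under 0.05, DESeq2 called 2, and 3 were higher when adjusted over the list alone (median 0.19, adjusted p = 0.17 with an estimated correlation): the noncoding H19 (2.34 ± 0.66, adjusted p = 0.0935 over all genes), Mest (0.93 ± 0.27, adjusted p = 0.0982) and Grb10 (0.39 ± 0.13, adjusted p = 0.153). H19 stood at 272 ± 266 CPM in Ct-Ct and 1380 ± 1599 in Ct-MetS, where 1 library, Ct-MetS_169, held 4551. Without that library the log2 fold change of H19, Ct-MetS against Ct-Ct, was 1.46 (adjusted p = 0.32) and that of Igf2, Ct-MetS against Ct-Ct, was 0.026 (adjusted p = 0.994). Igf2 (0.91 ± 0.59, adjusted p = 0.541) and Cdkn1c (0.22 ± 0.21, adjusted p = 0.716) did not pass in Ct-MetS, and Dlk1 was below the count minimum. Among genes of fibrosis Tgfb1 lay at 0.35 ± 0.11 (adjusted p = 0.111), Col1a1 at 0.51 ± 0.35 (adjusted p = 0.579) and Col3a1 at 0.49 ± 0.19 (adjusted p = 0.213) in Ct-MetS. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, passed in no comparison, at 123 ± 122 CPM in Ct-Ct and 316 ± 208 in MetS-MetS.

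Whether Plagl1 varied together with 3 gene lists from animal to animal was tested over the 23 libraries after removal of group means. The mean of the imprinted gene network had Pearson's r of 0.62 (permutation p = 0.0042, adjusted p = 0.013 over the 3 lists) and Spearman's rho of 0.61 (permutation p = 0.004, adjusted p = 0.012). Without the 2 libraries farthest from the median of Plagl1, r was 0.68. For extracellular matrix and fibrosis genes r was 0.55 (permutation p = 0.022, adjusted p = 0.034) and rho 0.55 (permutation p = 0.019), and r without those 2 libraries was 0.79. For fatty acid and triglyceride synthesis r was −0.23 (permutation p = 0.33) and rho −0.17 (permutation p = 0.48), with r at −0.15 without the 2 libraries. Without MetS-MetS_110, the library with muscle and keratin transcripts, the matrix relation had r of 0.50 with a permutation p of 0.058. Across the same libraries Plagl1 had r of 0.62 with the mean of stellate cell and fibroblast markers.

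**Figure D3:**
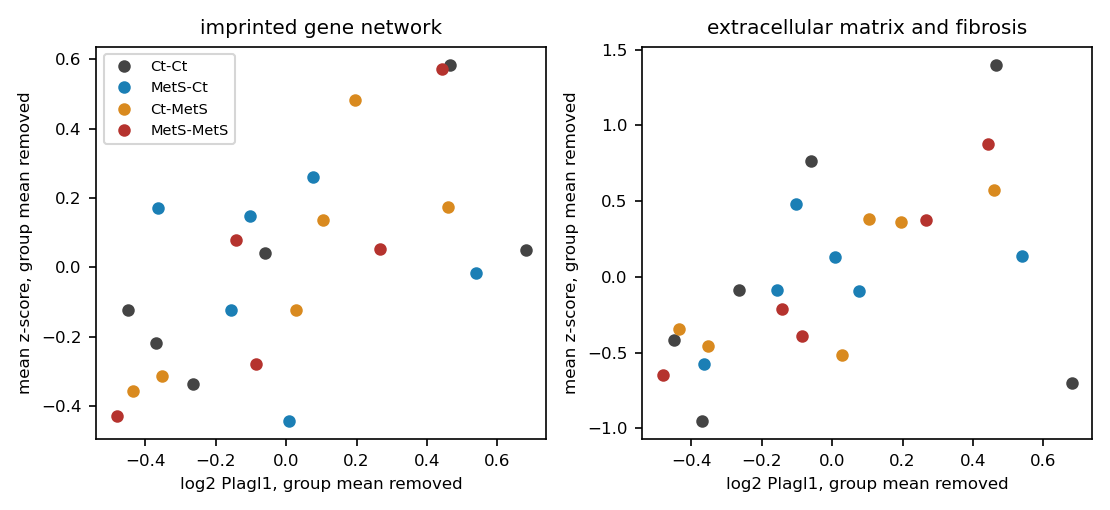
Log2 expression of Plagl1 (x axis, group mean removed) against the mean z-score of the imprinted gene network and of the extracellular matrix list (y axes, group means removed), with 1 point per library coloured by group (23 libraries). Pearson's r was 0.62 and 0.55.

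Ct-MetS and MetS-MetS shared 45 genes higher and 31 lower than Ct-Ct, with 0 in opposite directions. Groups simulated without change against the same control libraries shared 0. With no gene changed hardly any is called, so that count cannot tell how much overlap shared controls create among real calls. Independent lists of these sizes would share 2.60 and 1.44, a figure that leaves the shared controls out of account. With the Ct-Ct libraries split, so that each comparison had its own 3 controls, the mean over 20 splits was 0.90 higher and 0.85 lower. Fold changes of the 14466 genes had a correlation across genes of 0.41, against 0.48 in simulated unchanged groups and 0.26 with split controls; genes are not independent replicates. Their covariance was 0.0792 against 0.0369 simulated, a difference of 0.0423. For MetS-Ct with Ct-MetS the covariance was 0.0326 against 0.0369 simulated, a difference of −0.00426 (r 0.40, simulated 0.50, split controls 0.033), and for MetS-Ct with MetS-MetS 0.0482 against 0.0357, a difference of 0.0125 (r 0.31, simulated 0.46, split controls 0.13).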

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

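Libraries were picked out by 1 gap test fixed beforehand, and the counts of genes resting on MetS-MetS_110 were made only after that library's values had been seen. In each group the gap between the most extreme library and its nearest neighbour was set against the range of the group. Of 379 group values 42, or 11.08%, lay beyond the 95% limit, where chance gives about 5%, or 1 in 20, for independent values. These values were not independent. They also included genes named for their change in these data, such as Krt13 and Acta1, so the excess over 5% is partly built in.

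MetS-MetS_110 stood apart by transcripts of squamous epithelium and skeletal muscle. It held Krt13 at 338.8 CPM, Krt4 at 270.7, Acta1 at 357.8, Ckm at 128.3, Myh1 at 271.6 and Tnnt3 at 104.3, where the other 4 libraries of the group held at most 0.164. Its mean z-score was 4.018 for the muscle list and 0.763 for the stellate cell and fibroblast list. Of the 836 genes called in MetS-MetS, 45 had a level in this library above 5 times that of every other library, and 0 of these were called by edgeR without it. In the muscle list 0 of the other 4 MetS-MetS libraries lay above every Ct-Ct library.

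The same muscle genes were higher at low levels in Ct-Ct_10, with Acta1 at 2.305 CPM, Ckm at 0.9602, Myh1 at 1.997 and Tnnt3 at 0.4609 (list z-score 0.757). Ct-MetS_24 held Acta1 at 1.499 CPM, Ckm at 0.5354 and Myh1 at 1.071 (list z-score 0.708).

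In both groups nursed by MetS dams 1 library was low in Elovl6 and in another gene. Ct-MetS_50 held Elovl6 at 11.43 CPM against 36.0 to 69.0 in the rest of its group and Chrna4 at 2.763 against 10.1 to 21.6, with a synthesis list z-score of −0.744. MetS-MetS_39 held Elovl6 at 5.645 CPM against 27.3 to 46.3 and Pnpla3 at 0.7169 against 2.31 to 3.61. Its endoplasmic reticulum stress z-score was 0.643, and its 10 most abundant genes took 19.74% of counts, against 20.8% to 21.1%. The clock gene Dbp was lowest of each group in these libraries, at 2.33 CPM in Ct-MetS_50 and 2.78 CPM in MetS-MetS_39. The other groups did not show this pairing. In MetS-Ct the lowest Dbp, 3.28 CPM in MetS-Ct_53, came with Elovl6 at 53.5 CPM, against 7.56 in MetS-Ct_97. In Ct-Ct the lowest Dbp, 9.66 CPM in Ct-Ct_129, came with the highest Elovl6, 1092 CPM.

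Imprinted transcripts were high in single animals. H19 stood at 726.1 CPM in MetS-MetS_157, against 245.9 to 299.2 in its group, and Igf2 stood at 53.02 CPM in Ct-MetS_169 (7.46 to 11.9) and at 26.57 CPM in Ct-Ct_130 (3.49 to 6.70). MetS-MetS_157 also held Hamp2 at 3.937 CPM (0.371 to 0.664), with z-scores of 0.769 for inflammatory cytokines, 0.707 for interferon response and −0.674 for the cell cycle.

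Gtf2b stood at 44.98 CPM in Ct-Ct_130, against 30.4 to 33.4 in the other control libraries. Fabp2 stood at 56.44 CPM in Ct-Ct_33 (26.9 to 33.7), where mitochondrial genes took 5.332% of counts (3.76% to 4.23%). Tkfc stood at 236.4 CPM in MetS-Ct_97 (416.7 to 583.3), which had a bile acid list z-score of 0.582. Prodh stood at 310.3 CPM in MetS-MetS_109 (190.4 to 208.8). Pgpep1l stood at 6.102 CPM in MetS-Ct_70 (1.96 to 2.94) and at 0.7222 CPM in MetS-MetS_154 (1.80 to 2.54). Smoc2 was low in MetS-Ct_53, at 25.92 CPM (43.5 to 57.4), and in Ct-MetS_24, at 18.24 CPM (27.5 to 33.7). The pericentral z-score of MetS-Ct_85 was −0.758.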

How the results depend on the processing

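Thinned counts, clock covariates, DESeq2 size factors in edgeR and the removal of both MetS-MetS_110 and Ct-MetS_169 were chosen after the data were seen, and all other settings given here before. The direction of 1 of 246 named gene results reversed, in 1 setting. Over the settings, gene values stayed on the same side of the threshold in 7427 of 8451 cases, lost the call in 986 and gained it in 37. Among the 8451 were 58 in which the sign differed without a call. Counts in the other settings stayed within 1.5-fold of the main value, as with DESeq2 size factors or without robust estimation. No paired analysis was possible because no animal number occurs in more than 1 group. The sex covariate was not run, as all libraries fell in 1 class.

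DESeq2 Wald tests called 12 genes in MetS-Ct against Ct-Ct, 425 in Ct-MetS against Ct-Ct, 1346 in MetS-MetS against Ct-Ct, 97 in MetS-Ct against Ct-MetS, 140 for prenatal exposure, mean over both postnatal states (70.7% higher), 1038 for postnatal exposure, mean over both prenatal states, and 4 for the interaction of prenatal and postnatal exposure. Limma-voom with sample weights called 507 in Ct-MetS, 2447 in MetS-MetS, 218 for prenatal (73.9% higher) and 1465 for postnatal exposure. Without a filter, where more genes are tested, MetS-MetS had 457 calls and postnatal exposure 367. With a mean count of at least 50, MetS-Ct against Ct-MetS had 7 calls, and with limma-trend at a pseudocount of 5 it had 20. Fits to the groups compared alone, with fewer samples, called 47 in Ct-MetS and 0 in MetS-Ct against Ct-MetS. For the other settings the cause was not tested.

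Thinned to the smallest library, which lowers the depth, the data gave 82 calls in Ct-MetS against Ct-Ct, 6 in MetS-Ct against Ct-MetS and 0 for prenatal exposure. With clock covariates there were 278 in Ct-MetS, 143 in MetS-MetS against Ct-Ct (86 of them among the 836), 0 in MetS-Ct against Ct-MetS, 0 for prenatal exposure and 953 for postnatal exposure, mean over both prenatal states. Acta1 in MetS-MetS then lay at −0.401 (adjusted p = 0.949), and the cause was not tested. Without both MetS-MetS_110 and Ct-MetS_169 there were 25 in Ct-MetS, 305 in MetS-MetS (63.9% higher, against 53% with all libraries), 0 for prenatal and 283 for postnatal exposure. Lists passing camera with an estimated correlation numbered 0, 0, 0 and 1 in MetS-Ct, Ct-MetS, MetS-MetS and MetS-Ct against Ct-MetS, and by fry 0, 3, 7 and 4.

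With 1 library left out at a time, calls ranged from 12 to 246 in Ct-MetS, 219 to 1354 in MetS-MetS, 0 to 64 in MetS-Ct against Ct-MetS, 0 to 22 for prenatal and 349 to 923 for postnatal exposure. They stayed at 0 by edgeR for MetS-Ct and the interaction. Passing lists ranged from 14 to 19, 15 to 20, 11 to 17 and 14 to 22, and the share of variance between groups from 21.9% to 24.9%. The correlation of Plagl1 ranged from 0.483 to 0.801 with matrix, 0.558 to 0.682 with imprinted and −0.397 to −0.103 with synthesis genes.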

Other observations

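The tests of oxidation, synthesis and erythroid genes were chosen only after those results had been seen, and the random splits of the labels and the tests on Plagl1 before. Among genes that differ between the sexes in adult liver, some rose with postnatal exposure, although all libraries belong to 1 sex class. A1bg, higher in female liver, rose 5.75-fold (log2 fold change 2.52 ± 0.49 SE, adjusted p = 0.00831, higher in 11 of 11 exposed libraries), from 9.43 ± 4.09 CPM in Ct-Ct and 9.54 ± 9.10 in MetS-Ct to 67.2 ± 64.9 in Ct-MetS and 44.3 ± 23.4 in MetS-MetS. Slco1a1, an organic anion transporter higher in male liver, rose 8.40-fold (3.07 ± 0.61, adjusted p = 0.00896, higher in 9 of 11), and the complement gene C8a rose 1.52-fold (0.61 ± 0.12, adjusted p = 0.00784, higher in 11 of 11). In all, 3 of 26 female-biased genes rose over all genes and 6 when adjusted over the list alone (median 0.20, adjusted p = 0.551 with an estimated correlation). Of 19 male-biased genes 3 rose, and 4 when adjusted over the list alone (median 0.40, adjusted p = 0.465 with an estimated correlation). The female-biased count was 6 without MetS-Ct_149. A1bg, Slco1a1 and C8a kept their calls without any 1 library.

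In the bile acid list 1 of 28 genes rose with postnatal exposure (Slco1a1) and 2 fell, with 2 higher and 3 lower when adjusted over the list alone (median −0.043, adjusted p = 0.785 with an estimated correlation). Those that fell were Slc51b, a subunit of the basolateral bile acid exporter (log2 fold change −0.90 ± 0.19 SE, adjusted p = 0.0112), and Cyp2c70, the enzyme of muricholic acid synthesis (−0.52 ± 0.14, adjusted p = 0.0369, kept without 13 of the 23 libraries). In MetS-MetS the signal transducer of growth hormone Stat5b fell by 0.66 ± 0.13 (adjusted p = 0.0116), and Saa4, a serum amyloid gene, rose 2.10-fold (1.07 ± 0.24, adjusted p = 0.0169). Creb3l3, a transcription factor for lipid genes in liver, rose by 0.71 ± 0.14 (adjusted p = 0.0106). These 3 genes moved in the same direction in 5 of 5 MetS-MetS libraries and kept their calls without any 1 library. With clock covariates Stat5b lay at −0.44 (adjusted p = 0.119) and Saa4 at 0.66 (adjusted p = 0.159).

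The labels of the 23 libraries were reassigned at random to give 100 splits, the real one included. Only the real split reached its own count for postnatal exposure (611 calls, at most 223 in another split), for MetS-MetS (836, at most 12) and for Ct-MetS (138, at most 1). Random sorting of single animals therefore rarely gives such counts. Litter and dam are not given per animal, however, and pups that share a litter would make these shares too small, so chance is not excluded. The single gene of prenatal exposure was also matched by no other split (1, against 0), but it was lost without Ct-Ct_129 or Ct-Ct_139, MetS-Ct_70, MetS-Ct_97 or MetS-Ct_149 or MetS-MetS_109, MetS-MetS_154 or MetS-MetS_157, so the share of splits says little about it. For MetS-Ct against Ct-MetS 2 splits, the real one included, gave as many calls (11, at most 48). As another split gave more calls than the real one, chance is not excluded there. The 11 calls also fell to 0 without MetS-Ct_70, MetS-Ct_97 or MetS-Ct_120 or Ct-MetS_63, with clock covariates, and in a fit of these groups alone. For MetS-Ct and the interaction the splits decide nothing, because edgeR called 0 genes in the real one and 100 of 100 splits reach that whatever the data (at most 254 and 9). Splits that called 254 genes where the real one called 0, or 48 where it called 11, point to a structure of the samples besides the groups, such as single libraries that stand apart, and its source was not tested.

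In MetS-MetS 29 oxidation genes were higher (median log2 fold change 0.898, median SE 0.197) and 10 synthesis genes lower (−2.533, median SE 0.668). Time of day, depth, MetS-MetS_110 or fasting could account for this besides the exposure. With clock covariates the oxidation median was 0.91 (SE 0.232), which argues against time of day as its whole cause, and the fall to 8 calls came with larger standard errors. Lower depth is argued against by 28 oxidation and 9 synthesis genes still called after thinning. MetS-MetS_110 is argued against by medians of 0.964 (oxidation, median SE 0.211) and −2.506 (synthesis, median SE 0.744) without that library. For synthesis genes in MetS-MetS the median with clock covariates was −1.498 (median SE 0.77, 1 of 10 still called), so time of day and exposure cannot be told apart there. With postnatal exposure the median was −1.261 (median SE 0.417, against −1.527 without covariates, 6 of 9 still called). That comparison includes the same MetS-MetS libraries, so it cannot decide about time of day either. In Ct-MetS the 2 called members, Acaca and the fructose gene Tkfc, kept their calls, which argues against time of day as the whole cause for these 2 genes only. Fasting before sampling stays open for the oxidation genes, as 7 genes that fasting raises, chosen after their values had been seen, had a median of −0.404 with a large spread (SD 0.618, 3 higher and 4 lower), and was not tested for the synthesis genes.

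Erythroid genes rose with postnatal exposure, averaged over both prenatal states, and blood left in the liver pieces could raise them. Genes were chosen in 1 state, at an unadjusted p under 0.05, and measured in the other, which shares no library with it, as the 10 called genes (median log2 fold change 1.79) had been picked by their change and the whole list had a median of 0.471. The SEs given here are medians or means of the SEs of single genes, not errors of the summary values. In pups not exposed before birth 13 such genes had a median of 1.215 (median SE 0.338). There 4 globin genes, which red cells hold in far larger amounts, had a mean of −0.464 (mean SE 0.257), which argues against more blood in these pups. In pups exposed before birth 9 such genes had a median of 2.15 (median SE 0.413) and the globin genes a mean of 1.312 (mean SE 0.271), so more blood stays open there. The neutrophil and monocyte list, at a median of −0.153 (median SE 0.437), argues against leucocytes carried along in those pups. In pups not exposed before birth that list, at 0.261 (median SE 0.423), was too uncertain to decide. A change in erythroid precursors was not tested in either state.

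Plagl1 could follow the share of stellate and other non-parenchymal cells in each piece rather than regulate the genes it varies with. After the scores of the stellate, endothelial and Kupffer lists were removed, r within groups went from 0.554 to −0.158 for matrix genes and from 0.617 to 0.202 for the imprinted network, which is in line with cell share. Of genes with a similar mean count 2.90% of 999 had as high an r with the matrix list and 1.0% of 997 with the imprinted list, which argues against any gene of that level doing so. Plagl1 had r of 0.621 with the stellate list, 0.29 with the endothelial and 0.137 with the Kupffer list, the matrix list shares 0 genes with these lists, and the imprinted list shares Dcn with the stellate list. Removing the scores cannot separate the number of such cells from expression within them, so regulation by Plagl1 inside them stays open.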
